A study of Caenorhabditis elegans with 6 samples.

How the data were processed

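Gene expression was measured in Caenorhabditis elegans N2 larvae at the L2 stage, on 6 single-colour Affymetrix arrays. Per the labels' protocols, synchronized L1 larvae were fed HT115 bacteria carrying either the empty RNAi vector L4440 or the same vector with an insert against nhr-23, and were collected after 21 hours at 20 C from plates of 2% agarose. The labels place the insert in the ligand-binding domain of nhr-23. Biotinylated RNA was made from 4 ug of total RNA. The titles give 3 control and 3 RNAi samples and call them biological replicates. No more is said about whether they came from separate cultures, so p-values of single probe sets measure the spread between these samples. The growth protocol in the labels speaks of fly egg collection, which cannot refer to these worms, and it was not used.

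The authors deposited log2 values per probe set. MAS5, RMA and Partek are named in the submitters' processing notes, with no version and no statement of which made the table. Background correction and normalization are therefore known only from the values. The array medians lay between 5.12 and 5.18, and correlations between arrays lay between 0.985 and 0.997. No detection calls or scanner values were used here, so signal over background is not known for single probe sets, and changes of dim probe sets are compressed by an unknown amount. The number of arrays limits the precision.

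The table held 22625 probe sets, of which 77 were array controls and 22548 were tested, with no filter on low values and no further normalization. The platform annotation gave 1 gene symbol for 20766 probe sets, several for 887, and did not list 895. Entrez identifiers of 20701 single-gene probe sets were found in the WBcel235 gene table and took their symbol from it, and 65 kept the older symbol. No coordinates are given, because the array's genome build is not given in the sources used here. For gene lists, the probe set with the highest mean over the 6 arrays stood for each of 17118 genes, of which 2981 had more than 1 probe set. Within groups, the SD of the log2 difference between 2 arrays lay between 0.186 and 0.394, and at most 27 probe sets had identical values, so no array was treated as a duplicate.

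Probe sets were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 2-sided, group as the only term), with Benjamini-Hochberg adjustment over the 22548 probe sets and a threshold of 0.05. Before the data were examined, 38 gene lists were fixed, covering collagens, molting, epidermis, other tissues, stress responses and core cell functions. They were compared with other genes by limma's camera with a preset correlation of 0.01, for lists with at least 5 measured genes, and adjusted over the 38 lists. With that preset the genes of a list count as nearly independent, so its p does not measure the spread between arrays. Beside this test stand camera with an estimated correlation and limma's fry, which tests whether a list's genes move on balance one way. Furrow collagens were set against other collagens by an exact permutation test. The same test was run on the mean of each list. Members of a list were also adjusted over the list alone.

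Also fixed before the data were examined was the rule for named genes. It names nhr-23, nhr-25, dpy-7, dpy-5, rol-6, mlt-10, nas-37 and noah-1 whatever their values. It adds the 8 largest rises and 8 largest falls among genes past the threshold, which gave no gene, and members of each list past the threshold. From a list with none past it, the member with the smallest p may be named. Other genes named here were chosen after their values were seen. They are spp-13 and the list members past the threshold with the replicate number as a block.

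The replicate numbers in the titles were checked for pairing before the fits were compared. Deviations from the group means correlated across probe sets between same-numbered arrays, at 0.58 for replicate 1, 0.167 for replicate 2 and 0.573 for replicate 3. The mean of these was 0.44, against at most 0.31 for the other 5 pairings, and 5 of 6 arrays correlated best with their own number. The exception was control replicate 2, at 0.233 with RNAi replicate 1. By chance the titled pairing would rank first in 1 of 6 cases, so this evidence is weak. The numbers were still taken to pair the arrays, on the evidence of the values and not of any statement in the labels. Differences within pairs are differences between arrays of the same number, and values with the replicate block are given where they change a call.

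The fits were tested on simulated data of the size of this comparison, with 22548 probe sets. Without the block, 81% of 100 probe sets changed 2-fold and 97% of 100 changed 4-fold were recovered, with 0 false calls. With the block, 91% and 100% were recovered, with 8 false calls. The simulated noise was independent between probe sets and, without the block, held no difference between replicates that probe sets shared. These shares may therefore be too high for the real arrays. There a 6.60-fold rise of a nhr-23 probe set had a limma adjusted p of 0.993 without the block. Alternatives covered normalization, a filter on low values, the variance model, array weights, probe sets ending in _s_at or _x_at (6711), the probe set standing for a gene, the list test, the replicate block and each array left out in turn. Leaving out each pair of same-numbered arrays, and the block together with an estimated correlation, were added after the data had been seen. Leaving out 1 array kept the array of the same number in place and did not use the pairing. An offset shared by same-numbered arrays therefore moves those values. The criterion used to judge an exchange of the group labels was reworded once after its value was known. In its earlier form it counted the exchange as excluded, and in the present form it leaves it open. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.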

Results

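The data were log2 expression values of 22548 probe sets in 3 control and 3 nhr-23 RNAi samples of L2 larvae. NHR-23 is a nuclear hormone receptor needed for molting, the shedding and renewal of the cuticle at the end of each larval stage. The comparison asked which transcripts differed in larvae fed bacteria making nhr-23 double-stranded RNA (dsRNA) from those fed the empty vector.

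The 2 probe sets of nhr-23 differed between the groups in opposite directions. The probe set that was brighter in controls read 8.04 ± 0.27 (SD, n = 3) in the control arrays and 7.55 ± 0.10 (SD, n = 3) in the arrays labelled nhr-23 RNAi, a fall of 1.41-fold (log2 difference -0.49, SE 0.15). The dimmer one read 6.32 ± 0.45 (SD, n = 3) and 9.04 ± 0.49 (SD, n = 3), a rise of 6.60-fold (log2 difference 2.72, SE 0.30). In both probe sets the values of the groups did not overlap. By limma, adjusted over the 2 probe sets alone, which was decided after their values were seen, p was 0.0123 for the brighter and 1.04e-04 for the dimmer. Over all probe sets both had an adjusted p of 0.993, and with the replicate block that of the dimmer was 0.0370. The dsRNA fed to the worms covers part of nhr-23 itself, and which part of the gene each probe set reads is not known here. The fall in the brighter probe set goes with the labels. The rise in the dimmer one goes against them if it reads the worm's own transcript, and not if it reads the fed dsRNA. The directions given below are therefore those of the arrays as labelled.

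**Figure D1:**
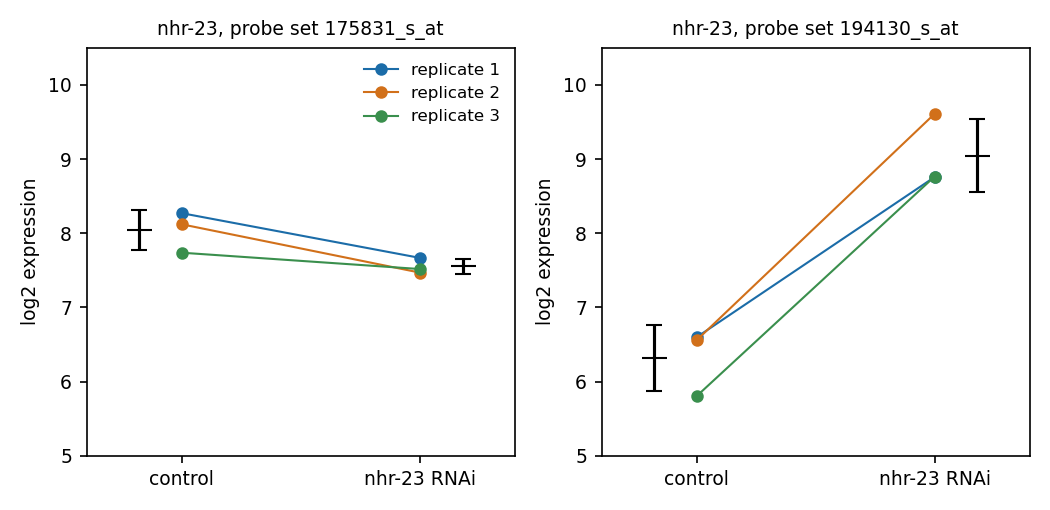
Log2 expression (y axis) of the 2 nhr-23 probe sets in control and nhr-23 RNAi arrays (x axis); points are arrays, lines join arrays of the same replicate number, and black bars give the group mean ± SD of 3 arrays. The brighter probe set (left) is lower in the RNAi-labelled arrays (7.55 against 8.04) and the dimmer (right) is higher (9.04 against 6.32).

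No single probe set passed the threshold over all probe sets tested. By limma, 0 of 22548 had an adjusted p under 0.05, and the smallest was 0.993. At an unadjusted p under 0.05 there were 833 probe sets, 483 higher and 350 lower in the RNAi-labelled arrays, where 1127 were expected by chance. The groups did not overlap in 9.5% of probe sets, against 10% by chance, a count that does not use the pairing. In all 3 same-number pairs 3669 probe sets were higher and 2497 lower in the RNAi-labelled array. Of these, 1 was higher and 46 were lower by at least 2-fold in the mean. Probe sets are not independent, and a share by chance was not computed for pairs. Under the replicate block 2 probe sets passed, the dimmer one of nhr-23 and that of spp-13, which encodes a saposin-like protein. The spp-13 value was 7.28 ± 0.80 (SD, n = 3) in controls and 5.62 ± 0.85 (SD, n = 3) in RNAi-labelled arrays, 3.17-fold lower (limma with the replicate block, adjusted p = 0.0457). At an unadjusted p under 0.05 the block gave 1344 probe sets, 524 higher and 820 lower.

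Of the 38 gene lists, 14 passed the threshold of limma's camera with the preset correlation, 11 lower and 3 higher in the RNAi-labelled arrays. Adding the replicate block, 19 passed, 15 lower and 4 higher, and these held all of the 14. With an estimated correlation 0 lists passed, with a smallest adjusted p of 0.646, or 0.446 with the block. Among the 14 the estimate ran from 0.0212 for hedgehog-related genes to 0.989 for furrow collagens, against the preset 0.01. With fry 0 passed, with a smallest adjusted p of 0.692, or 0.343 with the block. Exact permutation tests of the means of the 14 lists did not use the pairing. Their unadjusted p ran from 0.1 for oxidative phosphorylation, the smallest possible, to 0.6 for pharyngeal muscle. One member of any list passed when adjusted over the list alone without the block, exc-5, a guanine nucleotide exchange factor of the excretory canal (1.36-fold lower, limma adjusted p = 0.0320). A second exc-5 probe set differed by -0.02 log2 (limma unadjusted p = 0.815). Over all genes tested 0 members passed. All list results below are therefore calls of the preset correlation, under which another split of the same 6 arrays into groups of 3 gave 15 lists.

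The 5 furrow collagens, which form the circumferential furrows of the cuticle, had the largest median fall of the 14 lists. The list fixed held 6 genes, of which 5 were measured here. All 5 were lower in the RNAi-labelled arrays and in each of the 3 same-number pairs, with a median of 1.97-fold lower (camera adjusted p = 0.00108). The list mean was 9.97 ± 1.17 (SD, n = 3) in controls and 8.81 ± 0.90 (SD, n = 3) in RNAi-labelled arrays, and differed by -1.52, -1.08 and -0.86 log2 in the pairs of replicates 1, 2 and 3. The members were lower by 3.22-fold for dpy-3, 3.01-fold for dpy-8, 1.97-fold for dpy-7, 1.83-fold for dpy-9 and 1.57-fold for dpy-2. Without 1 array the log2 difference of dpy-7 ran from -1.69 (without control replicate 3) to -0.44 (without RNAi replicate 3) and that of dpy-2 from -1.29 to -0.04. Without RNAi replicate 3 those of dpy-8 and dpy-9 were -0.99 and -0.45. These values did not use the pairing. In the pairs of replicates 1, 2 and 3 dpy-7 differed by -1.35, -0.94 and -0.66 log2, and dpy-2 by -0.69, -0.67 and -0.60. In the fit with the block, 5 of 5 passed when adjusted over the list alone, and without it 0 did. The adjusted p of the list was 0.646 with an estimated correlation, and 0.124 by camera without RNAi replicate 3. With both replicate 3 arrays left out the list passed under the preset correlation. Both replicate 3 arrays lay below the other arrays of their group, by a median of -1.995 log2 in controls and -1.63 log2 in RNAi-labelled arrays for these genes, against -0.98 log2 between the groups, and of -0.60 and -0.68 log2 for the molting genes.

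Collagens named by other phenotypes were lower in 10 of 13 cases, with a median of 1.31-fold (camera adjusted p = 0.00303, and adjusted p = 0.646 with an estimated correlation). Their list mean differed by -0.56, 0.07 and -0.73 log2 in the pairs of replicates 1, 2 and 3. It was thus not lower in the replicate 2 pair, and 3 of the 13 genes were lower in all 3 pairs. In this list dpy-5 was 11.40 ± 0.08 (SD, n = 3) in controls and 10.38 ± 0.75 (SD, n = 3) in RNAi-labelled arrays, and rol-6 was 10.05 ± 0.42 and 9.19 ± 1.05. Neither passed the test. In the replicate 2 pair dpy-5 differed by -0.07 log2 and rol-6 by 0.05 log2. Without 1 array the log2 difference of rol-6 ran from -1.37 to -0.32, against -0.87 with all arrays. Camera's adjusted p was 0.195 without RNAi replicate 3 and 0.193 without probe sets ending in _s_at or _x_at. The list passed with both replicate 3 arrays left out. Replicate 3 lay below the other arrays of its group for these genes, by a median of -0.12 log2 in controls and -0.26 log2 in RNAi-labelled arrays. The furrow collagens minus these collagens gave 0.82 ± 0.99 (SD, n = 3) log2 in controls and 0.07 ± 0.52 (SD, n = 3) in RNAi-labelled arrays. This difference of -0.75 did not exceed the spread between arrays (exact permutation test, 2-sided, p = 0.3, where 0.1 is the smallest possible). The SD of the controls included control replicate 3, at -0.31 against 1.55 and 1.22 in the others. Within the same-number pairs the difference was -0.96, -1.15 and -0.14 log2, lower in 3 of 3 (exact sign-flip permutation test over pairs, 2-sided, p = 0.25, the smallest possible). The 146 cuticle collagens as a whole were split, 75 lower and 71 higher with a median of -0.002 log2. Their camera adjusted p was 0.120, and 0.00980 with the replicate block, where the direction was lower. The adjusted p was 0.446 with the block and an estimated correlation. With the block, 11 of the 146 passed when adjusted over the list alone. Of the 8 that were lower, 5 were the furrow collagens counted above, while col-140, col-176 and col-101 were higher, by 1.57-fold, 1.63-fold and 1.36-fold. The log2 difference of col-101 was 0.27 without RNAi replicate 3, against 0.44 with all arrays. The 128 genes named col, a family taken after the results were seen, had a median of 0.01 log2. Their camera adjusted p with the block was 0.627, adjusted over 390 families and not over the lists.

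**Figure D2:**
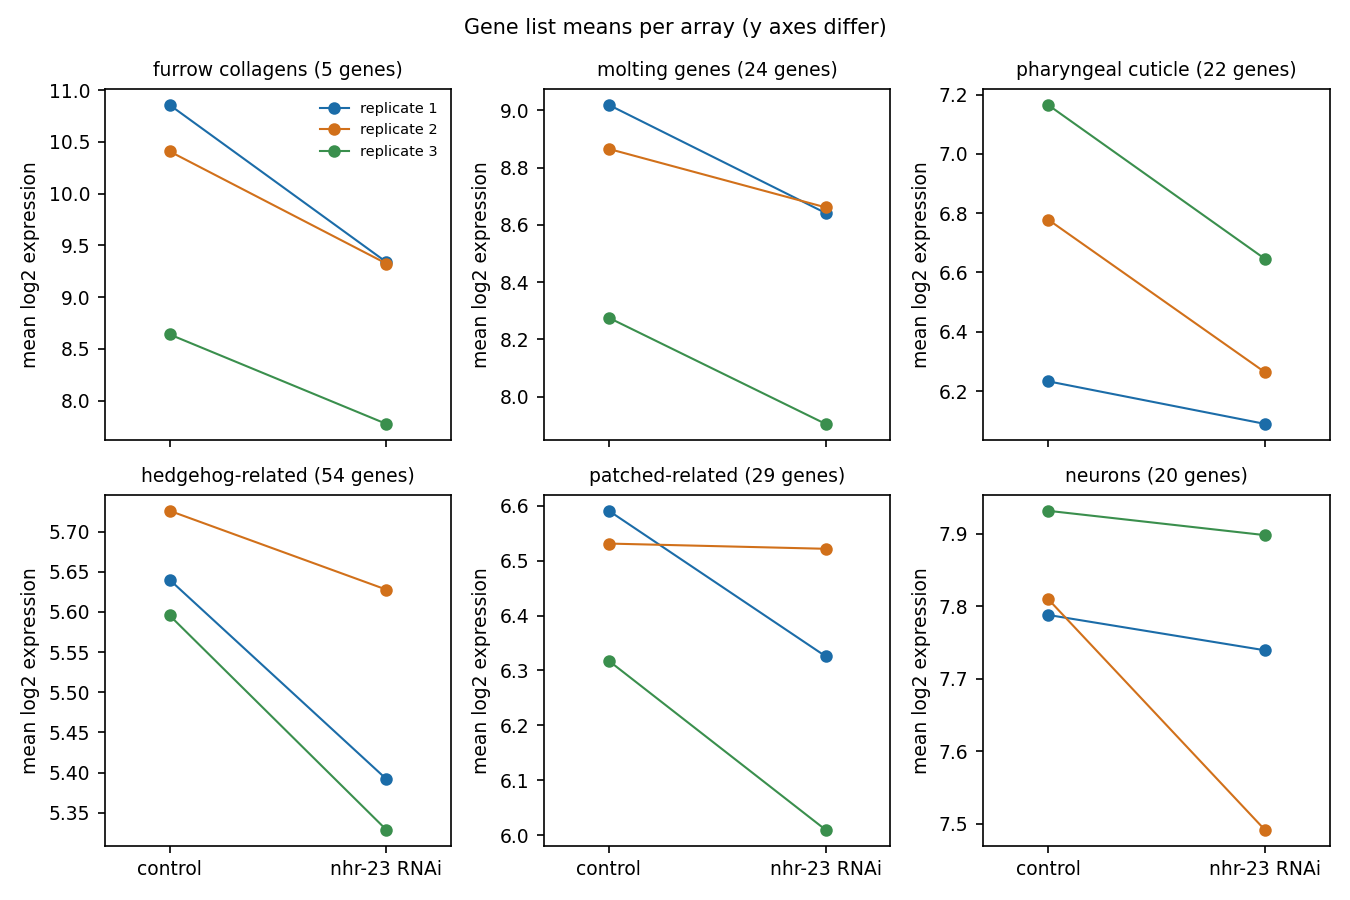
Mean log2 expression (y axis, scales differ) of 6 gene lists in control and nhr-23 RNAi arrays (x axis); points are arrays and lines join arrays of the same replicate number. The furrow collagen mean is lower in the RNAi-labelled array of each pair, and both replicate 3 arrays lie below the others in that list; the neuronal mean is lowest in RNAi replicate 2.

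Genes required for molting were called lower under the preset correlation. Of 24 measured, 23 were lower in the RNAi-labelled arrays, with a median of 1.22-fold (camera adjusted p = 4.63e-06, and adjusted p = 0.646 with an estimated correlation). The list mean was 8.72 ± 0.39 (SD, n = 3) in controls and 8.40 ± 0.43 (SD, n = 3) in RNAi-labelled arrays. This difference did not exceed the spread between arrays (exact permutation test without pairing, 2-sided, p = 0.5). In the same-number pairs the list mean differed by -0.38, -0.20 and -0.37 log2, lower in each. Under the replicate block 10 of 24 passed when adjusted over the list alone, and without it 0 did. Among the 10 were nas-37, an astacin protease of cuticle shedding, 1.70-fold lower, and noah-1, a zona pellucida domain protein of the apical matrix, 1.26-fold lower. Without control replicate 3 their log2 differences were -1.42 and -0.61, and without RNAi replicate 3 they were -0.32 and -0.05. In the same-number pairs they were -1.02, -0.93 and -0.35 for nas-37 and -0.51, -0.14 and -0.36 for noah-1. The molting gene mlt-10 was 7.92 ± 0.39 (SD, n = 3) in controls and 7.64 ± 0.51 (SD, n = 3) in RNAi-labelled arrays and did not pass. Its log2 difference of -0.28 ran from -0.56 to -0.07 without 1 array. A dimmer mlt-10 probe set, which did not stand for the gene in the list, read 6.50 ± 0.34 (SD, n = 3) and 5.88 ± 0.42 (SD, n = 3), a log2 difference of -0.62 (limma unadjusted p = 0.0443, and 7.96e-04 with the replicate block). Camera's adjusted p for the list was 0.195 without RNAi replicate 3, while the list passed with both replicate 3 arrays left out.

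Cuticlins and other zona pellucida domain proteins were lower in 29 of 40 genes, with a median of 1.05-fold (camera adjusted p = 0.0162, and adjusted p = 0.646 with an estimated correlation). As fixed, this list shares noah-1, noah-2, let-653 and fbn-1 with the molting genes. Taken as families after the results were seen, the 28 cutl genes and 6 cut genes did not pass. Their camera adjusted p were 0.299 and 0.361, and 0.211 and 0.407 with the block. These were adjusted over 390 families and not over the 38 lists. The unadjusted camera p without the block were 0.0397 and 0.0704. Regulators of molting and larval timing were lower in 15 of 20 genes, with a median of 1.09-fold (camera adjusted p = 0.0188, and adjusted p = 0.646 with an estimated correlation). The mean of these regulators was 7.12 in control replicate 3, against 7.42 and 7.31 in the other controls. In RNAi replicate 3 it was 6.975, against 7.26 and 7.29, while the groups differed by -0.11 log2. The nuclear receptor gene nhr-25 was 8.74 ± 0.19 (SD, n = 3) in controls and 8.54 ± 0.18 (SD, n = 3) in RNAi-labelled arrays, while its second probe set was 5.76 ± 0.14 and 5.94 ± 0.10, in the other direction. Neither passed. The adjusted p of the cuticlins was 0.232 without control replicate 1, 0.130 without control replicate 2 and 0.191 without RNAi replicate 3, and that of the regulators was 0.231, 0.0900 and 0.574. Astacin proteases (22 of 36 lower) and collagen processing enzymes (10 of 15 lower) had camera adjusted p of 0.120 and 0.0717, and passed with the replicate block, at 0.0145 and 0.00980. With the block and an estimated correlation their adjusted p were 0.454 and 0.562. Adjusted over the list alone, nas-4, nas-15 and nas-37 passed in the blocked fit, lower by 1.70-fold, 1.59-fold and 1.70-fold. The log2 difference of nas-4 ran from -1.35 without control replicate 3 to -0.28 without RNAi replicate 3. Epidermal antimicrobial peptides (16 of 26 lower) had 0.0995, and 0.0145 with the block, and an adjusted p of 0.454 with the block and an estimated correlation. Of these nlp-28, nlp-29 and nlp-31 passed in the blocked fit when adjusted over the list alone, lower by 1.31-fold, 1.32-fold and 1.36-fold. Without control replicate 3 their log2 differences were -0.17, -0.13 and -0.14.

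Hedgehog-related genes were lower in 34 of 54 cases, with a median of 1.07-fold (camera adjusted p = 0.0244), and patched-related genes in 22 of 29, with a median of 1.05-fold (camera adjusted p = 0.0143). Both had an adjusted p of 0.646 with an estimated correlation. In the blocked fit, 7 hedgehog-related genes passed when adjusted over the list alone, among them grl-15 (2.34-fold lower), wrt-2 (2.17-fold) and grl-7 (1.97-fold), and 4 patched-related genes passed, daf-6 (1.96-fold), ptr-10 (1.73-fold), ptr-4 (1.61-fold) and ptr-11 (1.49-fold). Without 1 array the log2 difference of each of these 7 named genes moved by over 1.5 times. Without RNAi replicate 3 it was -0.72 for grl-15, -0.48 for wrt-2, -0.56 for grl-7, -0.47 for daf-6, -0.18 for ptr-4 and -0.22 for ptr-11, and for ptr-10 it was -0.46 without control replicate 1. Without control replicate 3 it was -1.79 for wrt-2, -1.24 for ptr-10, -1.196 for ptr-4 and -0.86 for ptr-11. Each of these 7 named genes was lower in all 3 same-number pairs. Without the block 0 of either list passed. The hedgehog-related list had an adjusted p of 0.130 without control replicate 2, 0.0516 without control replicate 3, 0.164 without RNAi replicate 1 and 0.148 without RNAi replicate 3. The patched-related list had 0.0622 without control replicate 2 and 0.374 without RNAi replicate 3. Its mean differed by -0.27, -0.01 and -0.31 log2 in the pairs of replicates 1, 2 and 3. Both replicate 3 arrays lay below the other arrays of their group for the patched-related genes, by a median of -0.11 log2 in controls and -0.27 log2 in RNAi-labelled arrays, against -0.07 log2 between the groups.

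Genes of the pharyngeal cuticle fell, with 21 of 22 lower and a median of 1.31-fold (camera adjusted p = 2.15e-06, and adjusted p = 0.646 with an estimated correlation). The list mean was 6.73 ± 0.47 (SD, n = 3) in controls and 6.33 ± 0.28 (SD, n = 3) in RNAi-labelled arrays, and was lower in each of the 3 pairs. The list member phat-4 was 8.23 ± 0.23 (SD, n = 3) in controls and 7.78 ± 0.20 (SD, n = 3) in RNAi-labelled arrays. With the replicate block abu-10, 1.92-fold lower, passed when adjusted over the list alone, and its log2 difference ran from -1.48 without control replicate 1 to -0.49 without control replicate 3. Replicate 3 lay above the other arrays of its group for this list, by a median of 0.46 log2 in controls and 0.27 log2 in RNAi-labelled arrays. The camera call held without any single array, with a highest adjusted p of 0.0202.

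Markers of neurons (18 of 20 lower, median -0.14 log2, camera adjusted p = 4.24e-04), neuropeptides (40 of 44 lower, median -0.14 log2, 2.15e-06) and pharyngeal muscle (8 of 8 lower, median -0.19 log2, 0.0120) also fell. Each had an adjusted p of 0.646 with an estimated correlation. The synaptic vesicle GTPase gene rab-3 was 8.58 ± 0.05 (SD, n = 3) in controls and 8.32 ± 0.17 (SD, n = 3) in RNAi-labelled arrays, while its second probe set was 7.88 ± 0.05 and 8.00 ± 0.32. The gene flp-2, which encodes FMRFamide-like peptides, was 7.49 ± 0.23 and 7.15 ± 0.19. Without RNAi replicate 2 the adjusted p were 0.663, 0.496 and 0.960, and pharyngeal muscle turned higher. Without control replicate 3 those of neurons and neuropeptides were 0.0721 and 0.0765, and without control replicate 2 that of pharyngeal muscle was 0.0798.

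**Figure D3:**
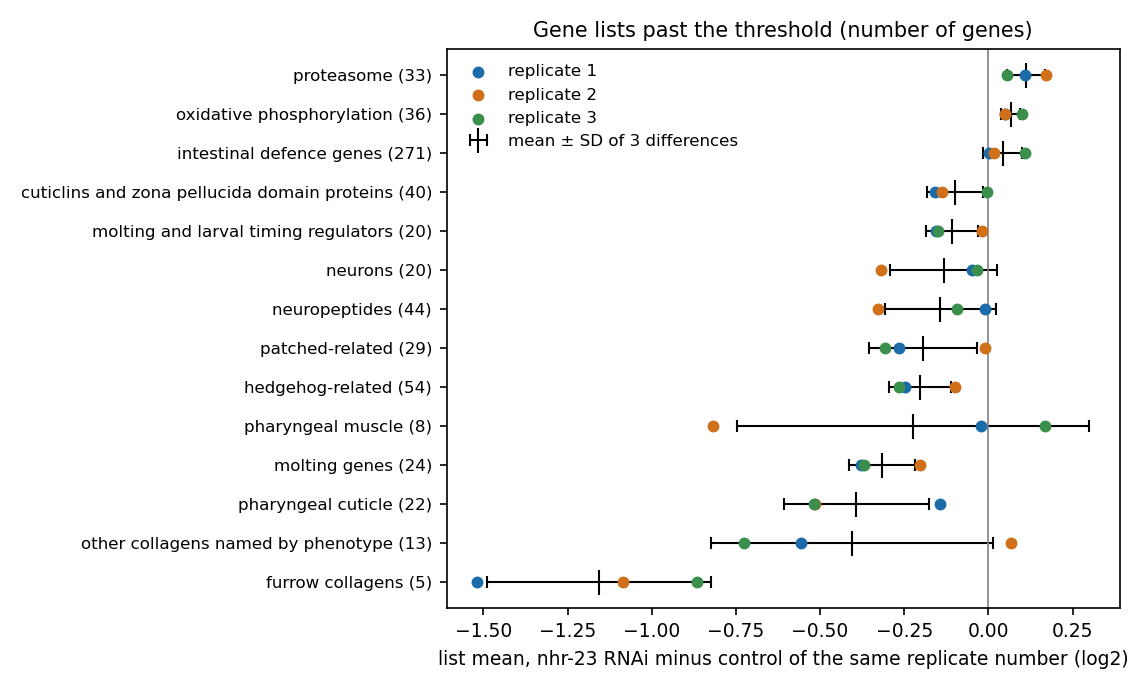
Difference of the list mean between the nhr-23 RNAi and the control array of the same replicate number (x axis, log2) for the 14 gene lists past the threshold (y axis, number of genes in brackets); coloured points are the 3 pairs and black bars their mean ± SD. Furrow collagens lie furthest below 0, at -1.52, -1.08 and -0.86, and in pharyngeal muscle replicate 2 stands apart at -0.82.

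A small rise was measured in 3 lists. Proteasome genes were higher in 31 of 33 cases, with a median of 1.08-fold (camera adjusted p = 4.24e-04, and adjusted p = 0.675 with an estimated correlation). Both replicate 3 arrays lay below the other arrays of their group for these genes, by a median of -0.17 log2 in controls and -0.24 log2 in RNAi-labelled arrays, against a median difference between the groups of 0.11 log2. Oxidative phosphorylation genes were higher in 31 of 36, with a median of 1.05-fold, and intestinal defence genes in 195 of 271, with a median of 1.04-fold (both camera adjusted p = 0.0120, and adjusted p = 0.646 with an estimated correlation). Of these 271 genes, 220 were clec genes, of which 160 were higher. Taken as families after the results were seen, spp, lys, irg, abf and ilys had unadjusted camera p from 0.353 to 0.863. The defence list is dim, with a mean of 4.88 in controls, below the array medians. The proteasome subunit gene pas-5 was 9.21 ± 0.07 (SD, n = 3) in controls and 9.41 ± 0.10 (SD, n = 3) in RNAi-labelled arrays. The member of the intestinal defence list that passed with the block, spp-13, was lower, against the direction of its list. Without control replicate 3 the adjusted p were 0.277 for the proteasome, 0.358 for oxidative phosphorylation and 0.358 for intestinal defence. The proteasome also had 0.179 without RNAi replicate 1 and 0.0581 without RNAi replicate 2, oxidative phosphorylation 0.0782 without RNAi replicate 1, and intestinal defence 0.148 without RNAi replicate 3.

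Histone genes (22 of 26 higher) had a camera adjusted p of 0.0868, and 0.0187 with the replicate block, and an adjusted p of 0.647 with the block and an estimated correlation. The other 19 lists passed in neither fit. They were nuclear hormone receptors without nhr-23, basement membrane, osmolyte and trehalose synthesis, cytosolic heat shock proteins, endoplasmic reticulum stress, detoxification enzymes, fatty acid metabolism, yolk proteins, body wall muscle, intestine, insulin-like peptides, germ line, major sperm proteins, epidermis and seam cells, coelomocytes and excretory system, cell cycle and DNA replication, ribosomal proteins, vacuolar ATPase and RNA interference. Their camera adjusted p ran from 0.103 for the germ line to 0.953 for yolk proteins. For osmolyte and trehalose synthesis the median was 0.07 log2 while the mean was -0.11 log2 and the test pointed lower. Median and test also differed in sign for nuclear hormone receptors, yolk proteins, epidermis and seam cells, coelomocytes and excretory system and ribosomal proteins, and mean and test for fatty acid metabolism. In the blocked fit osm-8 of the osmolyte list, 2.50-fold lower, and hsp-70 of the heat shock list, 1.36-fold higher, passed when adjusted over the list alone. The difference of hsp-70 between the group means was -0.42 log2 without control replicate 3, the other direction. In the same-number pairs it was 0.42, 0.37 and 0.55 log2, higher in each.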

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

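The test described here was chosen after the values were seen. Among the 77 array control probe sets, which the comparisons above do not use, 10 had every RNAi-labelled array above every control array, where 3.9 were expected by chance, and 1 had the reverse. Of the 14 probe sets for the bacterial bioB, bioC and bioD spike-in transcripts, 8 were among the 10, and the mean of the 14 was 0.26 log2 higher in the RNAi-labelled arrays. The cre control probe sets were not among the 10, with differences of 0.13, 0.25, 0.12 and 0.03 log2. Control probe sets share few transcripts, so they are not independent of each other. Groups of 3 arrays were not tested for single outlying arrays.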

How the results depend on the processing

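The count of probe sets past the threshold was 0 in every alternative except the replicate block, where it was 2, and the dimmer probe set of nhr-23 (log2 difference 2.72) became 1 of these. Between arrays left out in turn, the log2 difference ran from -0.64 to -0.38 for the brighter nhr-23 probe set, from 2.44 to 2.87 for the dimmer, and from -1.32 to -0.39 for furrow minus other collagens. Of 723 values of 44 named genes under alternatives, 721 kept their side and direction. The exceptions were both of the named gene vit-5, which reversed at -0.0489 log2 with array weights and -0.0025 without control replicate 3, and ran from -0.0025 to 0.171 between arrays left out in turn. None of the 44 genes passed over all probe sets in any setting, so keeping the side carries no information. Most were chosen for the smallest p in their list, and genes named only for the blocked fit, such as hsp-70, are not counted. Sizes did move: that of nhr-25 ran from -0.30 to -0.09 log2 between arrays left out in turn. The pseudocount alternatives did not apply to log2 values. A fit with no moderation was not run for the gene lists. The cause was not tested for any change given here, unless the alternative itself shows it.

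The count of lists past the threshold was 14. It was 19 with the replicate block, 6 of 35 without probe sets ending in _s_at or _x_at, where furrow collagens kept 2 measured genes and were not tested, 0 with an estimated correlation, 0 with fry, 0 with both the replicate block and an estimated correlation, and 9 to 17 between arrays left out in turn. With an estimated correlation the adjusted p was 0.646 for 13 of the lists and 0.675 for the proteasome, and with fry it was 0.692 for each of the 14. With the replicate block and an estimated correlation it was 0.446 for furrow collagens, molting genes, hedgehog-related, patched-related, molting and larval timing regulators and pharyngeal cuticle, 0.454 for cuticlins, 0.562 for the proteasome, 0.578 for other phenotype collagens, neurons and neuropeptides, 0.582 for oxidative phosphorylation, and 0.638 for intestinal defence genes and pharyngeal muscle. Of the 42 genes past the threshold with the replicate block when adjusted over a list alone, 32 moved by over 1.5 times without 1 array, 31 of them without a replicate 3 array, and 2 turned direction: noah-2, at 0.07 log2 without RNAi replicate 3, and hsp-70, at -0.42 log2 without control replicate 3. This count was added after the data had been seen. It compares group means without the pairing, so an offset shared by same-numbered arrays moves it, and it does not measure the spread of the pair differences. Within the pairs noah-2 differed by -0.47, -0.53 and -0.26 log2, and hsp-70 by 0.42, 0.37 and 0.55. The replicate block changed no other list call than those given with the results.

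Intestinal defence genes had an adjusted p of 0.0693 with quantile normalization, 0.0604 with the dimmest probe sets left out and 0.284 with array weights, and oxidative phosphorylation 0.128 with array weights. Without probe sets ending in _s_at or _x_at it was 0.193 for other phenotype collagens, 0.0930 for cuticlins, 0.197 for hedgehog-related, 0.130 for patched-related, 0.0800 for timing regulators, 0.0595 for oxidative phosphorylation and 0.0742 for the proteasome. Without both replicate 1 arrays it was 0.0541 for cuticlins. Without both replicate 2 arrays it was 0.177 for cuticlins, 0.373 for neurons, 0.272 for neuropeptides, 0.0911 for the proteasome and 0.423 for pharyngeal muscle, which reversed. Without both replicate 3 arrays it was 0.0964 for timing regulators, 0.522 for intestinal defence genes and 0.162 for oxidative phosphorylation. The other 11 of the 14 lists passed in that setting, furrow collagens and molting genes among them.

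Between arrays left out in turn, the adjusted p ran from 5.47e-07 to 0.124 for furrow collagens, 4.88e-08 to 0.195 for other phenotype collagens, 5.03e-10 to 0.195 for molting genes, 5.03e-04 to 0.232 for cuticlins, 0.00202 to 0.164 for hedgehog-related, 6.08e-04 to 0.374 for patched-related and 0.00202 to 0.574 for timing regulators. It ran from 0.00160 to 0.358 for intestinal defence genes, 9.30e-04 to 0.960 for pharyngeal muscle, which reversed without RNAi replicate 2, 5.33e-12 to 0.0202 for pharyngeal cuticle, 9.88e-08 to 0.663 for neurons, 7.46e-11 to 0.496 for neuropeptides, 0.00342 to 0.358 for oxidative phosphorylation and 7.46e-11 to 0.277 for the proteasome. Cuticle collagens, not past the threshold, ran from 0.00192 to 0.955 and reversed without control replicate 3, at 0.818. The 19 lists past the threshold in neither fit had 377 values under alternatives, of which 11 passed and 79 had the other direction. Signal over background is not known here, which limits what can be said of dim probe sets.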

Other observations

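The counts over splits of the 6 arrays were planned before the data were examined, except the count with the replicate block. The other tests in this part were chosen after the results were seen, and so was the scan of gene families that opens it.

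Families of genes that share a symbol prefix were compared with the other genes by limma's camera with the preset correlation. Of 390 families with at least 5 genes, 14 passed the threshold, and 11 of these also passed with the replicate block. Mitochondrial ribosomal protein genes were higher in the RNAi-labelled arrays, with 24 of 25 mrps genes (median log2 difference 0.12) and 32 of 34 mrpl genes (0.08). All 7 lpr genes, which encode lipocalin-related proteins, were lower, with a median log2 difference of -0.59 (adjusted p = 0.0234), and their mean was lower in each of the 3 pairs. Of the 13 dbd genes 12 were lower, with a median of -0.36 (adjusted p = 0.0378). With an estimated correlation no family passed, with an adjusted p of 0.985.

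The 2 probe sets of nhr-23 moved in opposite directions. The probe set dimmer in controls may read the fed dsRNA. Its lowest RNAi-labelled array lay 2.16 log2 above its highest control array, but such a gap also follows from the other explanations and does not favour this one. An exchange of the 2 group labels stays open: it would make the dimmer probe set, at 2.72 log2, a reading of the knocked-down transcript, but the brighter one would then be higher after RNAi. A rise of the worm's own nhr-23 transcription cannot be told apart from these, because the brighter probe set, at -0.49 log2, may read other transcripts. The parts of nhr-23 that the probe sets read would have to be known to decide.

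Furrow collagen, molting and pharyngeal cuticle genes were lower in the RNAi-labelled arrays. RNA degradation is argued against, since the difference between 3' and 5' probe sets of 4 worm control genes moved by at most 0.121 log2 between the groups. Both replicate 3 arrays differ from replicates 1 and 2 in the same genes, with a median of -1.63 log2 for furrow collagens and 0.27 for pharyngeal cuticle in the RNAi arrays and the same directions in controls, so these genes may mark a difference in age within the molting cycle. A single shift along that axis would move furrow collagens and pharyngeal cuticle in opposite directions. Both were lower in all 3 pairs (for pharyngeal cuticle the highest difference was -0.14 log2), so 1 such shift does not give both falls. For pharyngeal cuticle alone, a shift towards replicates 1 and 2 would also give a fall and stays open. Whether a difference in age would follow this axis was not tested. For furrow collagens and molting genes a shift cannot be told apart from an effect of RNAi. Across all genes, and not these lists alone, the effect of a pair correlated with the axis from arrays outside it at 0.141, -0.0648, 0.299 and 0.279. Of these 3 go with such a shift and 1 does not, and none is particular to these genes. An effect of nhr-23 on these genes is among the explanations left open, and no time course was analysed here.

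Neuronal, neuropeptide and pharyngeal muscle genes were lower in the RNAi-labelled arrays. The fall may come from the array of RNAi replicate 2, since without it the smallest adjusted p of the 3 lists was 0.496. A general loss of signal on that array could not be tested, because the array medians of the deposited values are aligned, and the median difference of 0.0217 log2 from the control of the same number decides nothing. An effect of nhr-23 RNAi in that sample was not tested.

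The 6 arrays make 10 splits into groups of 3, too few for a share under 0.05. For probe sets past the threshold, the real split gave 0 and the highest other gave 1, so that all 10 gave as many. For gene lists the real split gave 14 and the highest other gave 15, so that 2 of 10 gave as many. That other split set control replicates 1 and 2 and RNAi replicate 2 against the rest. With the replicate block, 4 splits part all 3 pairs, again too few for a share under 0.05. The real one gave 19 lists and 1 of 4 gave as many, while the highest other, with the pair of replicate 2 turned round, gave 15. In that other split the molting genes still passed, with a camera adjusted p of 1.13e-04, against 9.5e-15 in the real one. With the pair of replicate 3 or of replicate 1 turned round instead, it was 0.321 or 0.120.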
